A study of Mus musculus with 6 samples.

How the data were processed

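The series measured chromatin in B16 cells, a mouse melanoma line, by CUT&Tag. In this assay an antibody bound to chromatin in intact cells brings a protein A/G fusion of the Tn5 transposase to its target, and the transposase cuts and tags the DNA nearby. The labels describe 6 libraries made with 3 antibodies. Peak lists of 2 wild-type libraries were used, 1 for H3K4me3 (trimethylated lysine 4 of histone H3, a mark of active promoters) and 1 for p300 (the histone acetyltransferase encoded by Ep300, found at active enhancers and promoters). The 4 libraries for H3K9me3, in wild-type cells and in cells lacking Tdg, Trp53 or both, were not analysed here, so no genotypes were compared. Samples were grouped by their titles.

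Per the labels' protocols, each reaction used 1 µg of antibody, libraries were amplified with 18 PCR cycles and read as pairs of 150 bp. Per the submitters' processing notes, the build was mm10, and the tools named are Trim Galore, Bowtie2 2.2.5, Picard 2.22.4 and deepTools. The peak caller and any control library are not given in the sources used here. For the H3K4me3 and p300 libraries the authors deposited 1 peak list each in the narrowPeak layout. The names in each list run without a break, as from a single run of peak calling. This cannot tell 1 library from pooled replicates. Each deposited row gives start, end and summit. The deposited score of a peak is the whole part of 10 times its −log10 q, apart from 1 rounding tie. The deposited fold enrichment was read as a ratio of the summit to a background. Whether that background came from the same library or from a control is unknown. The deposited −log10 p and −log10 q belong to the same peak. All fold enrichments and −log10 q values named below are the authors', and they were used only to describe, rank or filter peaks within a list. PCR copies and fragments from repeated sequence can raise these values, and how either was filtered is not given in the sources used here.

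The peak lists state no read totals. The depth was therefore read from the values themselves, after they had been seen. A Poisson tail probability and a fold of (pileup + 1) over (background + 1) were solved for the summit pileup, and whole numbers of reads gave the deposited −log10 p within 0.002 for 99.98% of H3K4me3 peaks and 99.97% of p300 peaks. When −log10 p was raised by 1% in the first 2000 peaks of each list, whole numbers did so for 0.950% and 0.200%. On simulated peaks 491 of 491 pileups were recovered. The median summit held 80.0 reads in the H3K4me3 list (quartiles 45 and 129) and 39 in the p300 list (quartiles 28 and 59). The lowest background was 2.69 and 1.84 reads, a ratio of 1.46. This is the ratio of depths only if fragments were extended alike and each background came from its own library.

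Gene positions came from the RefSeq table of GRCm38.p6, whose primary chromosomes are those of mm10. The table gives the start and end of 21883 protein-coding genes on the chromosomes used, without strand, transcripts or exons. The planned measure at transcription start sites was therefore replaced by a gene end: a peak counted when it came within 1 kb of either annotated end of a gene. This counts promoters and 3′ ends together, misses promoters inside genes, and can credit a gene with its neighbour's promoter. Peaks shared at least 1 bp to count as overlapping. Peaks on the mitochondrial chromosome and on scaffolds were left out of all comparisons.

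Shares carry exact 95% binomial intervals, which cover counting error only. Observed shares were set beside 1000 random placements of the peaks within their own chromosomes, from which assembly gaps were not removed. Differences of medians carry 95% intervals from 1000 resamplings of 10 Mb blocks, which cover variation along the genome and not between cultures. Each of 23 gene lists was set beside 10000 random lists of protein-coding genes of the same size, and its percentile was the share of random lists with a smaller count plus 50% of those with the same count. A list was called above or below the random range when this percentile was over 97.5 or under 2.5. Random lists matched on H3K4me3 held as many genes with an H3K4me3 peak at an end, whatever its strength or width. Neighbouring genes of a list can share a peak, which scattered random genes rarely do, so percentiles of lists with clustered genes can be too extreme. With 1 library each for H3K4me3 and p300 there is no replicate check, and no p-value was computed across genes or peaks. The lists held 463 symbols, of which 457 matched a protein-coding gene. Lists, comparisons, most alternatives and the naming rule were chosen before the data were examined.

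Genes were named by a fixed rule. It names Tdg, Trp53, Ep300, Cdkn1a and Mdm2, up to 4 members of each list with the highest fold of a peak, the members of small minorities of 4 or fewer, any gene of the pigment list, the 10 p300 peaks of highest −log10 q with and without H3K4me3, and the 10 widest H3K4me3 peaks. Other names are said to be chosen after their values were seen. Some items the rule names are not reported here.

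The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. On simulated peaks a planted overlap of 60.5% was recovered as 60.5%, a planted width difference of 300.0 bp as 300.0 bp, and 38 of 40 intervals held it. Among unrelated simulated lists 3.80% fell outside the range. The alternatives were a −log10 q of at least 10, the upper 50% of each list by fold (the stronger part), the top 1% by fold left out, autosomes only, other definitions of overlap, other windows around gene ends, and all annotated genes. Fold is a ratio to background, so the stronger part by fold is not the part with most reads. H3K4me3 peaks of chromosome X had a higher median fold than autosomal ones, 7.58 against 6.21. Their median summit held fewer reads, 56 against 80. Alternatives that need genome sequence (repeats removed, random lists matched on CpG content, motifs at p300 summits) were not run.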

Results

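CUT&Tag peak lists of wild-type B16 melanoma cells were compared for H3K4me3 and p300, with 1 library each. The series concerns thymine DNA glycosylase (TDG), which removes thymine and oxidised cytosines from DNA, and its role in p53-deficient cancer. The wild-type lists show which promoters and p300-bound regions were marked in the parental cells. The H3K4me3 list held 27019 peaks on the nuclear chromosomes, with a median width of 757 bp (quartiles 484 and 1134) and a median fold enrichment of 6.24, and covered 23.2 Mb. The p300 list held 6512 peaks with a median width of 640.0 bp, a median fold of 5.76 and a coverage of 4.75 Mb. Read totals are unknown. Summits held a median of 80.0 reads for H3K4me3 and 39 for p300, and the smallest listed summits held 15 and 14. These values mix signal with depth and do not show which list missed more weak sites. A gene without a peak had none detectable at this depth.

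The genes the series is built around carried H3K4me3 in wild-type cells. Tdg (chromosome 10, 82629814 to 82650799) had an H3K4me3 peak of 1641 bp and fold 8.51 across an annotated end, and no p300 peak at either end. Its nearest p300 peak, of fold 5.91, lay 48310 bp away. Trp53, which encodes p53 (chromosome 11, 69580348 to 69591873), had an H3K4me3 peak of 2817 bp and fold 3.77 with a p300 peak of fold 4.56 inside it. Ep300 (chromosome 15, 81586209 to 81652077) had 2 H3K4me3 peaks at an end, the stronger of fold 6.19, and its nearest p300 peak lay 16504 bp away.

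The p53 target genes Cdkn1a and Mdm2 lay among several p300 peaks. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), had 6 p300 peaks within 50 kb of its ends. A p300 peak from 29090791 to 29091791 covered the lower end of the gene with a fold of 4.15, where no H3K4me3 peak came within 1 kb. An H3K4me3 peak of 2132 bp and fold 5.33 began inside the gene at 29093644 and contained another, weaker p300 peak. Mdm2, which encodes the ubiquitin ligase of p53 (chromosome 10, 117688875 to 117710758), had 2 H3K4me3 peaks and a p300 peak of fold 5.61 at its upper end. A stronger p300 peak of fold 7.20 lay 6588 bp beyond it.

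**Figure D1:**
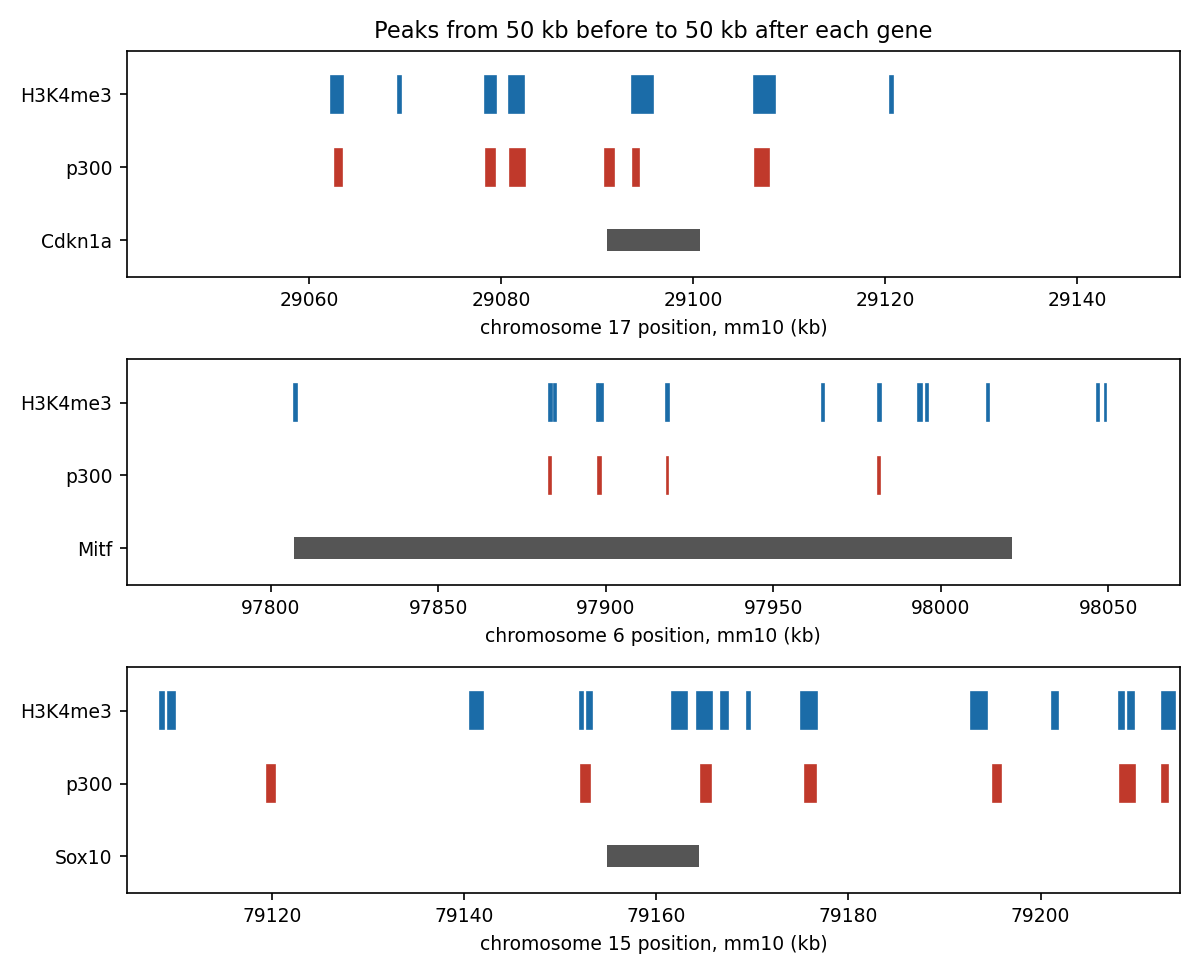
Peaks around Cdkn1a, Mitf and Sox10, with position in kb (mm10) on the horizontal axis, H3K4me3 peaks in blue, p300 peaks in red and the annotated gene in grey. Within 50 kb of their ends, Cdkn1a has 6 p300 peaks and Sox10 has 7, and 4 p300 peaks lie inside Mitf.

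The comparison of the lists asked where p300 was found relative to H3K4me3. Of 6512 p300 peaks, 5568 overlapped H3K4me3, a share of 85.5% (84.6 to 86.4%). Random placements gave 1.78% on average and 2.26% at most, so the overlap was 48.1 times the random level. The placements spread over whole chromosomes, so open chromatin taken up by both libraries would also exceed them. The excess therefore cannot tell such uptake from p300 bound at H3K4me3. In the other direction 5715 of 27019 H3K4me3 peaks overlapped p300, which is 21.2% (20.7 to 21.6%) against 0.437% at random. The p300 summit itself lay inside an H3K4me3 peak in 80.9% of peaks. Among the stronger part of each list by fold, the share of p300 peaks with H3K4me3 was 62.1%.

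Both lists were concentrated at gene ends. Of the p300 peaks 37.6% (36.4 to 38.7%) came within 1 kb of an end of a protein-coding gene, 8.70 times the random share of 4.32%. Of the H3K4me3 peaks 43.2% (42.6 to 43.8%) did so, 9.77 times the random share of 4.42%. At gene ends 97.6% (96.9 to 98.2%) of p300 peaks overlapped H3K4me3, and away from gene ends 78.2% (76.9 to 79.5%) did. The p300 peaks without H3K4me3 were rarely at a gene end, with 59 of 944 (6.25%), against 2386 of 5568 (42.9%) of those with it. Away from gene ends and overlapping H3K4me3 was the most frequent combination, with 48.9% of all p300 peaks. Promoters inside genes count as away here, and 72.7% of p300 peaks and 76.0% of H3K4me3 peaks lay in a gene or within 1 kb of it, against 42.7% and 42.6% at random.

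H3K4me3 peaks with p300 were wider and stronger than those without. Their median width was 1074 bp against 689 bp, a difference of 385 bp (362 to 407). Wide peaks meet a p300 peak more easily by chance, and random placements alone gave a difference of 174 bp (45.0 to 309), below the observed one. The median fold was 6.55 with p300 and 6.15 without, a difference of 0.40 (0.32 to 0.49). Within the p300 list, peaks with and without H3K4me3 had median folds of 5.76 and 5.80, and the difference of -0.041 had an interval from -0.166 to 0.0991, which includes 0. With the summit inside H3K4me3 as the criterion it was 0.163 (0.0506 to 0.279), and with an overlap of at least 50% of the p300 peak 0.140 (0.0111 to 0.229), so the difference depended on how overlap was defined. By other measures p300 peaks with H3K4me3 were the stronger, with a median −log10 q of 15.8 against 14.4 (difference 1.46, 0.864 to 2.19), and the wider, by 100.5 bp (74.5 to 120.5).

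The share of H3K4me3 peaks with p300 rose with H3K4me3 strength. In a split into 5 classes of equal size by −log10 q, chosen after the data were seen, it went from 5.66% to 36.0% at gene ends and from 10.5% to 42.1% away from them. In each of the 5 classes the share was higher away from gene ends, for example 33.0% against 21.5% in class 4.

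**Figure D2:**
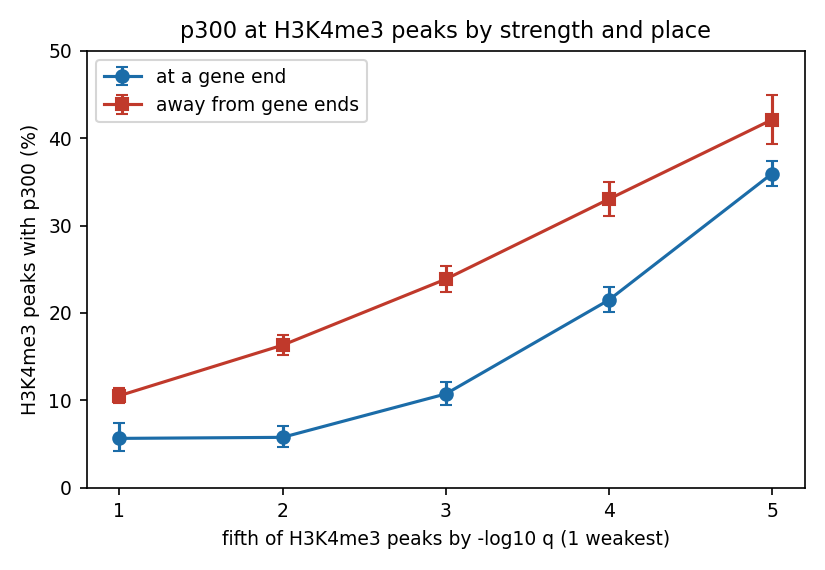
Share of H3K4me3 peaks that overlap p300 (vertical axis, percent) in 5 classes of the H3K4me3 list by −log10 q (horizontal axis, weakest first), at gene ends in blue and away from them in red, with exact 95% binomial intervals. In the strongest class the shares are 36.0% and 42.1%.

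By gene, 11041 of 21883 protein-coding genes (50.5%, 49.8 to 51.1%) had H3K4me3 at an end and 2957 (13.5%, 13.1 to 14.0%) had p300 there. p300 within 50 kb of an end was found for 9532 genes (43.6%). Of the genes with p300 at an end, 98.95% had H3K4me3 at an end. Of the genes with H3K4me3, 26.5% had p300. Only 31 of 10842 genes without H3K4me3 at an end (0.286%) had p300 there, Cdkn1a among them.

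The pigment cell genes stood high for both proteins. H3K4me3 lay at an end of 20 of 25, a count reached by 28 of 10000 random lists, and p300 at an end of 11, reached by 2. Within 50 kb, 22 of the 25 had p300, which 0 random lists reached. In the stronger part of the H3K4me3 list by fold, the share with H3K4me3 was 28.0%, with a percentile of 26.0, on the other side of the random middle, and p300 at an end had a percentile of 94.2, inside the range. That part is ranked by a ratio to background and not by reads, so it can drop peaks with many reads. Against random lists with as many H3K4me3-marked genes, p300 at an end had a percentile of 99.6. Mitf, the master transcription factor of the lineage, had the highest H3K4me3 fold of the list at 8.16, and 11 H3K4me3 and 4 p300 peaks inside the gene. Sox10, another transcription factor of pigment cells, had 7 p300 peaks within 50 kb, the strongest of fold 5.24. Rab38 and Myo5a, which act in melanosome transport, had nearby p300 peaks of fold 10.4 and 9.48, and Tyrp1, a melanin synthesis enzyme, one of 9.34. Pmel, which forms melanosome fibrils, had 2 p300 peaks in its annotated span, the stronger of which, of fold 5.33, also lies in Cdk2. Tyr, the first enzyme of melanin synthesis, had H3K4me3 of fold 5.16, and Tyr, Kit and Slc24a5 had no p300 peak within 50 kb. Ednrb had no H3K4me3 in the gene or within 1 kb, although a p300 peak of fold 6.17 lay within 50 kb of it.

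The p53 target list had the largest share of genes with p300 at an end. It was 19 of 34, which 0 of 10000 random lists reached, also when the random lists held as many H3K4me3-marked genes, where 7.75 genes were the mean. The matching left out H3K4me3 strength, with which the share of peaks with p300 rose. H3K4me3 was at an end of 29. Rrm2b, a ribonucleotide reductase subunit, and Ccng1, a cyclin, had H3K4me3 of fold 11.5 and 11.3, and Ddb2 and Ercc5, which act in nucleotide excision repair, 10.3 and 10.7. The strongest nearby p300 peaks were those of Ccng1 at 9.15, Sfn at 8.85, Plk2 at 8.71 and Bbc3, which encodes the apoptosis inducer PUMA, at 8.38. p300 lay within 50 kb of 25 of the 34.

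Repair and chromatin genes were mostly marked by H3K4me3. Of the 23 excision repair and demethylation genes 21 had it, with Tet1 at fold 11.1, Neil3 at 10.7, Mbd4 at 10.5 and Mutyh at 9.92. The exceptions were the DNA methyltransferase genes Dnmt1 and Dnmt3a, which had it inside the gene. p300 was at an end of 7 of them, with a percentile of 98.3 among all lists and 75.7 among lists matched on H3K4me3, and within 50 kb of 15 (percentile 98.0, matched 73.4). Among lists matched on gene length these percentiles were 96.4 and 94.5, inside the range, as was p300 at an end in the stronger part by fold (95.4). The strongest was at Ogg1, which encodes the glycosylase for oxidised guanine, at fold 10.6. Of the 19 genes for H3K9 methylation and its readers, 18 had H3K4me3, led by Atf7ip at 13.8 and Setdb2 at 11.2, and 8 had p300 at an end, led by Atf7ip at 9.57 (percentile 99.9, matched 94.8). The list had p300 within 50 kb for 15 (percentile 99.9, matched 95.7). H3K4me3 marked 17 of 19 genes of the H3K4 methylation list and 15 of 16 of the acetylation list, and p300 was at an end of 4 and 3 of them and within 50 kb of 12 and 10, all within the random range. In the stronger part by fold, H3K4me3 stayed above the range for excision repair (percentile 98.4) but not for the H3K9 (94.7), H3K4 (75.3) and acetylation (77.7) lists.

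Genes of proliferation and signalling were marked more often than random lists. H3K4me3 was at an end of 24 of 27 cell cycle genes, 14 of 17 apoptosis genes, 17 of 18 immediate early genes and 18 of 19 genes of MAPK signalling and its feedback. p300 was at an end of 10, 8, 7 and 6 genes of the cell cycle, immediate early, apoptosis and MAPK lists, respectively. The counts within 50 kb were 20, 17, 14 and 15 in that order. Pcna, the replication clamp, and Mcm4, a replicative helicase subunit, had p300 of fold 9.14 and 9.18 at an end. Mcl1, which blocks apoptosis, had none at an end and a peak of 11.1 within 50 kb, and Dusp6, a phosphatase of ERK, had 4.16 at an end and 9.69 within 50 kb. Among lists matched on H3K4me3, p300 at an end lay inside the random range for all of them, with percentiles of 94.0, 96.0, 96.4 and 75.1 in the same order. Within 50 kb the matched percentiles were 95.9 for the cell cycle and 95.7 for the MAPK list, inside the range, and 99.98 for the immediate early and 99.1 for the apoptosis list, above it. Egr2 was the immediate early gene without H3K4me3 at an end or p300 within 50 kb, and had an H3K4me3 peak of fold 5.62 inside the gene. In the stronger part of the lists by fold, H3K4me3 lay inside the range for all of these lists, with percentiles of 75.04 for the cell cycle, 85.55 for apoptosis and 87.5 for MAPK, and of 14.2 for the immediate early list, with 22.2% of its genes. In that part p300 was at an end of 5.26% of the MAPK genes (percentile 43.6). The percentile was 77.5 for p300 at an end of the apoptosis genes and 82.6 for p300 within 50 kb of the MAPK genes, all inside the range. Among lists matched on gene length p300 at an end of the MAPK genes had a percentile of 96.4, also inside it. Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes, and Orc1 were the cell cycle genes without H3K4me3 at an end.

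Interferon and nucleic acid sensing genes had p300 at an end less often than lists matched on H3K4me3. H3K4me3 was at an end of 18 of 25 (percentile 98.3, but 90.7 when whole genes were counted and 96.4 in the stronger part by fold), with Stat2 the strongest, Tlr3 at 11.4 and Ifih1, a sensor of double-stranded RNA, at 11.2. p300 was at an end of 1, Mavs, with a percentile of 7.69 among all lists and 1.52 among lists matched on H3K4me3, where the mean was 4.81 genes. Within 50 kb of an end 13 had p300 (percentile 79.7, matched 51.9), in the random range. All 15 genes of the MHC class I list, mostly genes of antigen presentation, had H3K4me3, led by Erap1 at 10.8. Of these, 5 had p300 at an end and 12 within 50 kb (percentile 99.8, matched 92.1, and 86.0 in the stronger part by fold). Of 32 ribosomal protein genes 31 had H3K4me3, with Rps24 the exception (in the stronger part by fold percentile 50.2), while p300 was at an end of 7 and within 50 kb of 20, with percentiles of 90.7 and 98.4 among all lists and 32.7 and 56.2 among lists matched on H3K4me3. The count within 50 kb had a percentile of 90.5 in the stronger part by fold. The list of the dedifferentiated, invasive melanoma state was inside the random range for all measures, with H3K4me3 at 14 of 23, p300 at an end of 5 and within 50 kb of 13. Its strongest H3K4me3 at a gene end was at Snai2 with 9.08, and Tead1 had a stronger peak inside the gene at 9.70.

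Markers of other cell types were mostly without H3K4me3 at their gene ends. It was found at 0 of 12 epithelial genes, at Cd68 alone of 13 myeloid genes and at Apoa1 alone of 12 hepatocyte genes. Of 15 lymphocyte genes Tcf7 and Cd4 had it, of 14 stromal genes Col1a1 and Pdgfrb, of 11 muscle genes Ckm and Tnnt2, and of 16 germline genes Hormad1 and Tex14. These lists lay below the random range, but the muscle list did not with windows of 500 bp (percentile 2.81) or 2 kb (4.68) or in the stronger part by fold (3.72), nor the germline list in that part (3.18). Counted in the gene or within 1 kb, H3K4me3 was at 8 of 14 stromal genes (57.1%, percentile 45.0), inside the range, while the other lists named so far stayed below it. The neural list had it at 4 of 13 genes, Gfap, Map2, Syt1 and Tubb3, and at 7 with whole genes counted, inside the range. The Hox genes had it at 13 of 39, with Hoxc6 at 10.2 the strongest. This was below the range, but not with a window of 2 kb (percentile 11.2), on autosomes alone (2.70) or among lists matched on gene length (4.62). p300 was at an end of none of the epithelial, hepatocyte, lymphocyte, myeloid, stromal and neural genes, of Tnnt2 in the muscle list, of Hormad1 in the germline list and of 2 of 39 Hox genes. These counts at an end lay inside the range. Lists of 18 or fewer genes could not lie below it there. A count of 0 of 18 gives a percentile of 3.69, 0 of 15 one of 5.57 and 0 of 12 one of 8.68. With whole genes counted, the Hox count of 2 (percentile 0.63) and the lymphocyte count of 0 (1.85) lay below the range. Counts of p300 within 50 kb were 0 for the epithelial and hepatocyte lists, below the range, and 7, 5, 5, 5, 7, 5 and 18 for the lymphocyte, myeloid, stromal, neural, muscle, germline and Hox lists, inside it. In the stronger part by fold 2.56% of the Hox genes had p300 within 50 kb, below it. Among lists matched on H3K4me3 the muscle count had a percentile of 98.7.

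**Figure D3:**
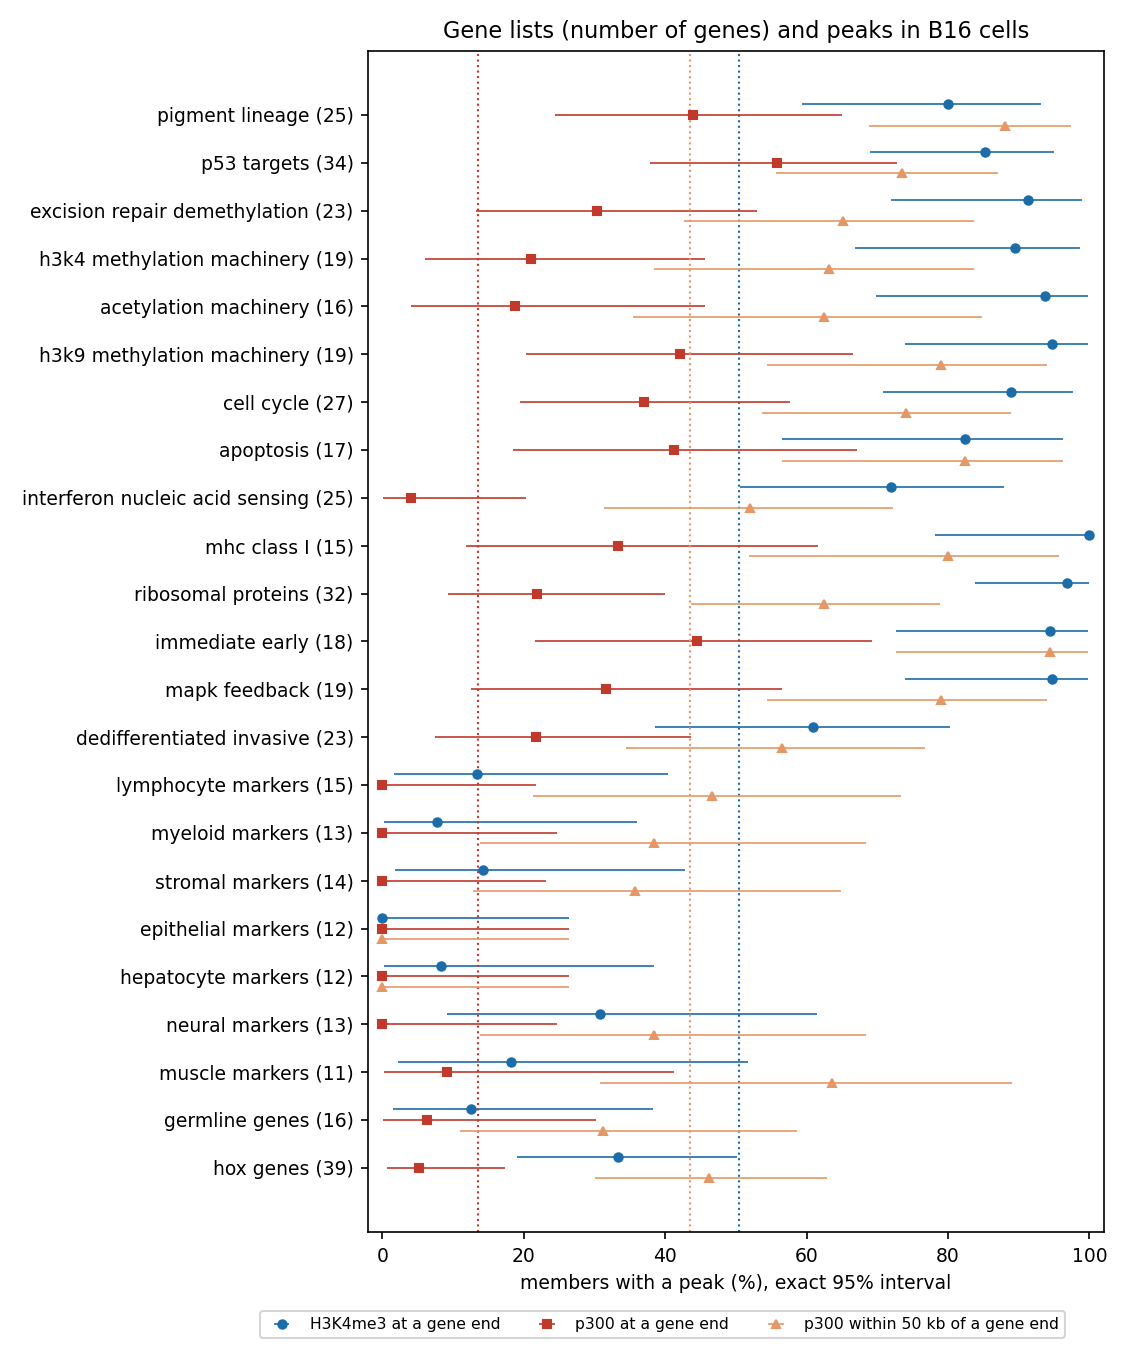
Share of each gene list (rows, with the number of genes) with H3K4me3 at a gene end (blue circles), p300 at a gene end (red squares) and p300 within 50 kb (orange triangles), in percent with exact 95% binomial intervals. Dotted lines give the shares of all protein-coding genes, 50.5%, 13.5% and 43.6%, and the p53 targets have the highest share with p300 at an end.

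In all, 41 of the 69 list percentiles lay outside the random range, where 3.45 is the nominal number for random lists. The percentiles are not independent, since p300 at an end also counts within 50 kb. Random lists drew on all protein-coding genes, among them 1110 olfactory receptor genes with H3K4me3 at 0. A list without such genes can lie above the range whatever its function, so the tally does not show marking particular to these lists. The calls for H3K4me3 in the muscle list, for both p300 measures in the excision repair list and for p300 at an end in the MAPK list were marginal, with counts equal to a limit of the range. For H3K4me3 13 lists lay above and 8 below, for p300 at an end 8 above and 0 below, and for p300 within 50 kb 10 above and 2 below. For p300 at an end, lists of 18 or fewer genes could not lie below, since 0 of 18 gives a percentile of 3.69. Among lists matched on H3K4me3 the tallies for p300 were 2 above and 1 below at an end, and 5 above and 2 below within 50 kb. With the stronger part of each list by fold, H3K4me3 put 3 lists above the range and 6 below, p300 at an end 4 above, and p300 within 50 kb 7 above and 3 below. The lists still above for H3K4me3 were the p53 targets, excision repair and MHC class I.

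The p300 peaks of highest −log10 q that overlapped H3K4me3 lay mostly away from protein-coding genes. Of the 10 strongest, 9 overlapped no protein-coding gene, and 5 shared both borders within 50 bp with an H3K4me3 peak. The first lay on chromosome 2 from 98666289 to 98667313 with a fold of 13.7, 1034617 bp from the nearest gene end, that of Lrrc4c. Others lay on chromosome 14 from 19415728 to 19419352 (fold 17.5) and on chromosome 9 from 35305222 to 35305589 (fold 24.3, nearest gene Rpusd4). The exception lay in Kdelr2, on chromosome 5. The strongest without H3K4me3 were a pair on chromosome 13 near Prl2c2 and Prl2c5, members of a prolactin gene family, the first with a fold of 11.7. Others had Panx1, Fem1a, Gstp2, Aff3, Zan, Gm42048 and Lgals3 as nearest genes. Of the 10 widest H3K4me3 peaks, 5 lay between 123537970 and 123623730 on chromosome 8, between Gas8 and Rhou, the widest with 19382 bp, and 3 near the start of chromosome 9. The others were on chromosomes 10 and 11. Whether these wide or strong peaks came from sequence held in many copies was not looked at. They cannot be read as broad active regions.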

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

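All tests in this part were chosen after the results were seen. Both lists held peaks outside the chromosomes compared. The mitochondrial chromosome, a DNA without histones, held 5 H3K4me3 peaks and 3 p300 peaks. Their folds were at most 3.67 and 2.55, but their −log10 q reached 117 and 1165. On the nuclear chromosomes the median −log10 q was 31.9 for H3K4me3 and 15.6 for p300. On unplaced or unlocalized scaffolds there were 19 H3K4me3 peaks and 14 p300 peaks, of which 9 in each list lay on a single scaffold. With no control library analysed here, a count of 0 was the level they were set against.

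The strongest p300 peaks stood apart from the rest. Of the 66 peaks in the top 1% by −log10 q, 16.7% (8.63 to 27.9%) were within 1 kb of a gene end, against 37.8% of the others, which argues against strong binding at gene promoters as their common source. Both borders lay within 50 bp of an H3K4me3 peak's in 24.2% (14.5 to 36.4%) of them and in 2.31% of the others. This is consistent with reads from sequence held in many copies that pile up in both libraries, and 5 of the 66 lay within 1 kb of the outermost annotated position of a chromosome. Of the 30 H3K4me3 peaks of highest fold, 11 lay within 1 kb of such a position, as did 11 of all 27019. Repeat content was not looked at without genome sequence, so strong open sites away from genes stay open, and no biological explanation was tested.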

How the results depend on the processing

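The alternatives of leaving out matching borders, counting the whole gene, and matching lists on H3K4me3 or gene length were chosen after seeing the data. The share of p300 peaks with H3K4me3 was 84.1% at a −log10 q of at least 10, 62.1% in the stronger part of each list by fold, 79.0% with at least 50% of the p300 peak covered and 80.9% with the summit inside. The share of H3K4me3 peaks with p300 was 18.0%, 15.0%, 19.4% and 19.5% in that order, and 23.2% with H3K4me3 peaks merged within 1 kb. Keeping the stronger part drops peaks from both lists, which lowers an overlap by construction. It ranks peaks by a ratio to background and not by reads, so lost list calls need not mean weak peaks. All these shares stayed far above random placement, and shifting the p300 peaks of each chromosome together gave 1.78% on average. The fold difference of p300 peaks was 0.215 in the stronger part, 0.140 with 50% covered and 0.163 with the summit inside, and the cause was not tested. The width difference of H3K4me3 peaks was 334.5 bp at −log10 q of at least 10, 225 bp in the stronger part, 438 bp with 50% covered, 432.5 bp with the summit inside and 430.0 bp after merging, always wider with p300.

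The share at gene ends followed the window by construction. For p300 it was 34.6% at 500 bp, 41.6% at 2 kb, 44.5% with all annotated genes and 72.7% in the gene or within 1 kb. For H3K4me3 it was 37.3%, 48.1%, 50.1% and 76.0%, and 45.6% at −log10 q of at least 10 and 49.4% in the stronger part. Genes with p300 at an end numbered 1516 in the stronger part, where fewer peaks remain. Lists outside the random range numbered 9 for H3K4me3, 3 above and 6 below, and 4 for p300 at an end in the stronger part, and for lists matched on H3K4me3 3 for p300 at an end and 7 within 50 kb. In the stronger part the pigment list had H3K4me3 at 28.0% (percentile 26.0), the immediate early list at 22.2% (percentile 14.2), and the MAPK list p300 at an end at 5.26% (percentile 43.6), each on the other side of the random middle, and the cause was not tested. Of the 69 list results, 67 kept their call at −log10 q of at least 10, 68 without the top 1%, 66 on autosomes, 68 at 500 bp, 65 at 2 kb, 65 with whole genes, 65 matched on gene length, 68 without matching borders and 49 in the stronger part, and of the 46 p300 results 32 did when matched on H3K4me3. Calls lost when matched on gene length were H3K4me3 in the Hox list (percentile 4.62), p300 at an end in the excision repair (96.4) and MAPK (96.4) lists and p300 within 50 kb in the excision repair list (94.5). Calls lost with whole genes were H3K4me3 in the interferon list (percentile 90.7) and in the stromal list, which went from 2 to 8 of 14 genes, and p300 in the pigment list went from 11 to 19 of 25. Calls gained were p300 below the range in the Hox (2 of 39, percentile 0.63) and lymphocyte (0 of 15, percentile 1.85) lists. At −log10 q of at least 10 both p300 calls of the MAPK list were lost (90.4 at an end, 95.9 within 50 kb), at 2 kb p300 at an end in excision repair (97.03) and on autosomes p300 within 50 kb in the ribosomal list (96.7). p300 at an end in the MHC class I list was above the range at 2 kb (99.02), and barely without the top 1%, on autosomes and without matching borders. The other results for all peaks or all genes stayed within their intervals, or within 1.5 times for counts. Removing repeats, matching on CpG content and both motif alternatives were not run. No paired analysis was possible because H3K4me3 and p300 have 1 library each, and the depth limits which weak p300 peaks could be listed.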

Other observations

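All gene families and tests in this part were chosen after the data were seen. Genes for replication-dependent histones stood out for p300. H3K4me3 lay at an end of 32 of 57 (56.1%, 42.4 to 69.3%), close to all genes, while p300 lay at an end of 25 (43.9%, 30.7 to 57.6%), above the range of random lists and of those matched on H3K4me3, and within 50 kb of 41. These genes are clustered and share neighbouring peaks, so their counts are not independent. Zinc finger (Zfp) genes had H3K4me3 at 280 of 367 (76.3%) and p300 at an end of 64 (17.4%, percentile 98.6, matched on H3K4me3 7.46). They had p300 within 50 kb of 169 (46.0%, percentile 83.1), which was low among matched lists (0.215). Genes for complex I of the respiratory chain had H3K4me3 at 37 of 37 and p300 at an end of 8.

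Several tandem gene families had little of either. H3K4me3 was at 0 of 1110 olfactory receptor genes, at 2 of 353 vomeronasal receptor genes, at 0 of 56 keratin-associated protein genes and at 0 of 71 defensin genes. p300 lay within 50 kb of 46, 14, 0 and 5 of them. Type I interferon genes, also in tandem, had H3K4me3 at 1 of 18 and p300 within 50 kb of 10 (percentile 83.9, matched 99.5). Neighbours in tandem can share a p300 peak, so these counts are not independent and cannot be read as an excess. The H3K4me3-free stretch with most genes ran on chromosome 2 from 85051176 to 90474962 with 227 genes, mainly olfactory receptors. On chromosome 1 from 172503784 to 175624612 a stretch of 48 genes held Aim2 and its IFI200 relatives, cytosolic DNA sensors and related proteins, with no H3K4me3 and no p300. Cdkn2a and Cdkn2b lay alone in an H3K4me3-free stretch of 329 kb on chromosome 4, with 1 p300 peak in it. It was longer than 94.6% of the 26998 such stretches, and 612 were at least as long and held 2 or more genes.

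Groups of p300 peaks, joined across short gaps after leaving out matching borders, numbered 115 with 3 or more peaks. Those with 6 peaks were 2 on chromosome 8 between 123567140 and 123621982, 1 at Lmna, which encodes nuclear lamins, and 1 at Gm40363. The pair on chromosome 8 had no protein-coding gene within 10 kb, and other kinds of gene were not looked up. The pair lay in the region that held 5 of the 10 widest H3K4me3 peaks. Reads from sequence held in many copies were not ruled out there. Those with 5 included Cdkn1a, Tex14 and a region with Gstp1 and Gstp2. Within 50 kb of such a group lay 2.04% of all genes, 4 of 25 pigment genes (Pax3, Dct, Sox10 and Gpnmb) and 4 of 34 p53 targets (Cdkn1a, Bbc3, Bax and Pidd1), with percentiles of 99.8 and 99.1 among lists matched on H3K4me3.

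H3K4me3 peaks of chromosome X had p300 less often than autosomal ones, 55 of 555 (9.91%) against 21.4%. The median background at H3K4me3 peaks was 6.49 reads on X and 12.4 on autosomes, and at p300 peaks 3.25 and 6.0. Whether these backgrounds came from the libraries themselves is unknown. Matching X to autosomal peaks on the H3K4me3 summit pileup in 20 classes gave 0.637 (0.397 to 0.789) of the expected number. The p300 reads were not matched, so this cannot decide whether fewer reads in both libraries are the whole cause. Matching on pileup and on gene end lowered the expected number from 86.3 to 66.8 and gave 0.823 (0.532 to 1.03). Fewer reads together with the place of X peaks relative to gene ends may account for the lower share on X. The width of the interval leaves a remainder open. No biological explanation was tested.

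H3K4me3 peaks away from gene ends had p300 more often than gene-end peaks of like strength. The odds ratio was 2.26 (2.05 to 2.48) after matching on summit pileup in 50 classes, and 2.40 (2.2 to 2.6) after matching on pileup and width in 10 classes each, against 0.947 (0.887 to 1.02) unmatched. These values argue against p300 peaks that follow H3K4me3 strength, alone or with width. Enhancers and inner promoters among the peaks away from gene ends stay open as sources, as does uptake of open chromatin by both libraries, and no biological explanation was tested.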
